A study of Mus musculus with 27 samples.

How the data were processed

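The series holds 27 ChIP-seq samples of mouse macrophages. Kupffer cells high in F4/80 and positive for Tim4 were sorted from C57BL/6J mice on a control diet or on a diet that models NASH, per the labels. H3K27ac, LXR, ATF3 and P300 each had 2 libraries per diet. The 10 input samples and the 1 H3K27ac library of peritoneal macrophages were not analysed here, so no value is given against input and the planned comparison with peritoneal macrophages was not made. Groups were taken from the sample labels. The replicate numbers of the labels were not used to pair libraries.

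Per the submitters' processing notes, Bowtie2, HOMER and DESeq2 and the builds mm10 and GRCm38 were used, with versions and roles not given in the sources used here. The H3K27ac values were deposited as a signal, tags per window scaled by HOMER to 10000000 tags per library on mm10, per the file headers. The 70300 windows (124 to 550 bp, median 204) were merged reproducible ATAC-seq peaks of Tim4-positive cells, per the file headers, from a control list and a list named for 20 weeks on the diet. The headers of the NASH LXR and P300 lists carry another name, so the time on the diet of those libraries may differ and is not given in the sources used here. HOMER assigned each window to the nearest gene, and 40.5% lay in introns, 31.4% between genes and 21.0% at promoters. For LXR, ATF3 and P300, 1 list per diet was deposited, with a reproducibility (IDR) score and, for LXR and P300, an enrichment score for each site. The lists joined both libraries, per the file headers, at an IDR threshold of 0.05 for LXR and P300. The threshold for ATF3 is not given in the sources used here, and its score column has no name and was read as the IDR score from its place in the other lists. No IDR score was lower than 540 in any list. Scores are the authors' own and were used only to rank or compare sites within a list. The ATF3 lists were not matched in length by rank, because 58.0% and 66.1% of their sites shared the highest IDR score.

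Multiplying each H3K27ac value by the library total in the header gave whole tags within 0.02 for 100% of the values of each library. Libraries held 9468035 and 22615879 tags (control) and 18749728 and 19231109 (NASH), of which 908503, 2004872, 1614096 and 1520727 lay in the windows. Windows without a tag made up 11.6%, 10.1%, 10.9% and 10.8%. A count of 0 allows up to 3 tags, which is 3.17, 1.33, 1.60 and 1.56 normalised tags. A single window on chromosome 2 (98667086 to 98667288) held 2.44%, 2.39%, 4.02% and 5.17% of the tags in windows. The 12 windows without a gene name stayed out of the gene sums and held 0.0580%, 0.0609%, 0.108% and 0.132% of these tags. Replicate libraries were compared before they were averaged. Their log2 values had a Pearson correlation across windows of 0.847 (control) and 0.887 (NASH), and chi-square per degree of freedom was 2.47 and 1.97, above sampling noise, so each library counted once. Intervals are exact 95% binomial intervals. Intervals and floors cover counting error only, as no molecular identifiers were used here.

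Tests were planned on raw counts with edgeR's quasi-likelihood test. Because the deposited values are normalised, the main test was limma-trend on log2(value + 1), with windows kept by edgeR's filterByExpr on the recovered tags (35947 windows, 11593 genes). Windows were called at an adjusted p under 0.05 and an absolute log2 change of at least 1, gene sums at an adjusted p under 0.05. All adjusted p-values are from the Benjamini-Hochberg method. A count test on the recovered tags (edgeR, TMM) called 1357 windows raised and 1130 lowered, and 857 genes raised and 764 lowered. The 26 gene lists held 429 names, of which 369 occur in the table. They covered Kupffer cell identity, LXR targets, lipid-associated and scar-associated macrophages, AP-1 and ATF factors, inflammatory NF-κB genes, interferon, TGF-β and BMP, Notch, cholesterol synthesis, fatty acid synthesis, antigen presentation, growth factors and matrix, scavenger receptors and phagocytosis, lysosome, iron and heme, housekeeping genes, and markers of 10 other cell types. Lists of at least 5 measured genes (21 lists) were tested against all other genes with camera at a preset correlation of 0.01, and likewise the 9 sets of windows with control-only, shared or NASH-only sites of each factor. Sites were matched by an overlap of at least 1 bp (bedtools), and shares of windows with a site were compared by two-sided Fisher's exact tests in a family of 18. Sites within 20000 bp of a gene were counted for that gene, with gene spans of the same build.

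Named windows were the 10 per direction with the smallest adjusted p among called windows whose diets do not overlap, 1 per gene and without predicted genes. Named list genes were the called members with the smallest adjusted p, up to 4 per direction, which gave 68 genes, 1 of which is not reported here. Loci for the factors were listed beforehand, together with the sites of the highest enrichment score per factor and class, which for ATF3 could not be ranked. Other list members that are named, such as C1qa, Trem2, Abca1, H2-DMa, Ly6c2 and Ccr2, were chosen after their values were seen.

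On simulated tags for the same windows, with 2 libraries per diet and a dispersion of 0.0353, limma found 7.46%, 31.3% and 54.5% of windows changed 2-, 3- and 4-fold, with 2 false calls among 35947 windows. edgeR found 11.9%, 41.8% and 62.1% with 7 false calls and DESeq2 1.49%, 16.4% and 37.9% with 0. Camera found 5 of 5 lists of windows changed 1.5-fold and called 0 of 15 unchanged ones. The simulated windows were drawn independently, so this run cannot show how often camera calls lists of correlated members falsely. In the data the estimated correlation was 0.23 for the lipid-associated list, 0.030 for the Kupffer identity list and −0.017 for the scavenger list. Site shares of gene lists were set against 10000 random lists (seed 1) matched over 10 strata of site number, and H3K27ac at windows was matched over 20 bins of its level. Alternatives covered the test, the scaling, the filter, the pseudocount, the fold threshold, each library left out, a replicate block, the windows summed per gene, the set test and the overlap and ranking of sites. Motifs at factor sites were not analysed here because no genome sequence was used. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, bedtools 2.31.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.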

Results

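ChIP-seq, which sequences the DNA bound by a chosen protein or carrying a chosen histone mark, was performed on Kupffer cells, the resident macrophages of the liver, sorted by high F4/80 and by surface Tim4 from C57BL/6J mice. The mice had been fed a control diet or a diet that models non-alcoholic steatohepatitis (NASH), a fatty and inflamed liver. Of the 27 samples, 4 were Kupffer cell libraries of H3K27ac, the histone acetylation found at active promoters and enhancers, with n = 2 per diet. The nuclear receptor LXR, the stress-induced transcription factor ATF3 and the acetyltransferase P300, which is recruited to active enhancers, were each profiled in 2 libraries per diet. The 10 input samples and 1 H3K27ac library of peritoneal macrophages were not analysed here. H3K27ac was given in 70300 windows with a median width of 204 bp, on genome build mm10, as tags scaled by the authors to 10000000 per library, here called normalised tags. The control libraries held 9468035 and 22615879 tags in total and the NASH libraries 18749728 and 19231109. Of these, 9.60% and 8.86% (control) and 8.61% and 7.91% (NASH) fell in the windows, a median of 6 and 11 against 8 and 8 tags per window. For the factors, the authors' lists of reproducible sites were used, 1 list per factor and diet made from both libraries. Nothing in the labels says that the libraries of a group came from separate animals. The p-values of single windows and genes thus measure the spread between these libraries, which may be technical. Camera at the preset correlation and Fisher's exact test take genes or windows as their units. Their p-values therefore do not measure the spread between libraries, however small they are.

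The first comparison asked where the regulatory landscape of Kupffer cells differed between the diets. H3K27ac rose with the NASH diet beside Traf1, an adaptor of tumour necrosis factor receptors, in an intergenic window at −1809 bp from its transcription start site (TSS; chromosome 2, 34963481 to 34963681), from 6.97 ± 3.90 to 86.5 ± 17.9 normalised tags (mean ± SD, n = 2 per diet, as for all means here). It also rose in an intron of Tnfaip3, which encodes the NF-κB inhibitor A20 (chromosome 10, 19008358 to 19008558), from 12.7 ± 0.11 to 87.3 ± 15.3, and in an intron of Gpnmb, a glycoprotein of lipid-laden macrophages (chromosome 6, 49037015 to 49037215), from 1.72 ± 0.55 to 40.0 ± 1.46. H3K27ac fell in an intron of Timd4, which encodes the phosphatidylserine receptor Tim4 and so 1 of the markers of the sort (chromosome 11, 46811586 to 46811786), from 103 ± 13.7 to 4.24 ± 3.06. It fell likewise in an intron of Pcolce2, an enhancer of procollagen processing (chromosome 9, 95681871 to 95682071), from 89.0 ± 4.85 to 8.15 ± 1.72.

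Changes are given as log2 of NASH over control on the scale of log2(value + 1), which understates the change of low values. On the authors' scaling the median of all tested windows lay at −0.26 and that of all tested genes at −0.29, and each log2 change below is relative to that median. The limma adjusted p-values and calls with this scaling test the change before that subtraction. Rises were therefore tested as smaller, and falls as larger, than printed. A gene called lower can thus lie near the median, as Id3 did (−0.11, limma adjusted p = 0.0223). Relative to the median the 5 windows changed by 3.79 (SE 0.36, limma adjusted p = 4.32e-05) at Traf1, 2.93 (SE 0.28, 6.99e-05) at Tnfaip3, 4.19 (SE 0.44, 9.74e-05) at Gpnmb, −4.17 (SE 0.38, 1.35e-05) at Timd4 and −3.05 (SE 0.30, 1.35e-05) at Pcolce2. The other windows named for the smallest adjusted p among raised ones lay in introns near Pik3r6 (3.36, SE 0.35), Myo3b (3.78, SE 0.45), Xylt1 and Dnmbp, between genes near Rab21 (3.74, SE 0.42) and Dennd4c, and at −388 bp from the TSS of the lactate transporter gene Slc16a1 (2.56, SE 0.28). Xylt1 went from 1.06 ± 1.49 to 38.9 ± 8.99 normalised tags. The Dennd4c and Dnmbp windows held no tag in either control library, where a count of 0 allows up to 3.17 and 1.33 normalised tags, and 33.9 ± 8.70 and 21.6 ± 3.37 under the NASH diet. Among lowered windows were those in introns of Sash1 (−2.89, SE 0.34), Arl15 (−2.45, SE 0.34) and St6galnac3 (−3.86, SE 0.50), in a 3' UTR near Cdc42bpg (−1.92, SE 0.27) and between genes near Aebp2 (−3.85, SE 0.39). Windows near Pik3c3 and Mog went from 27.6 ± 1.66 and 27 ± 0.66 to 0.27 ± 0.37 in both cases, and 1 near Ldoc1 from 25.6 ± 3.27 to no tag in either NASH library, where up to 1.60 and 1.56 normalised tags are allowed. The adjusted p of these 15 windows lay between 2.30e-05 and 2.93e-04. The Dnmbp call ended without NASH library 1 (adjusted p = 0.0983) or NASH library 2 (0.0710).

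Of 35947 windows tested, 720 were raised and 1651 lowered (adjusted p under 0.05 and a log2 change of at least 1, before the median was subtracted). With factors that set the median near 0 (TMM), 1191 were raised and 902 lowered, a share raised of 56.9% in place of 30.4%, and 720 raised and 902 lowered windows were called with both scalings. Within 1000 bp of a TSS, 139 of 15245 tested windows were raised and 448 lowered, and farther away 581 and 1203 of 20695. Without NASH library 1 the counts were 195 raised and 1334 lowered, without NASH library 2 they were 176 and 684, and without control library 1 they were 841 and 850.

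Summed over the windows annotated to each gene, H3K27ac was called raised at 335 and lowered at 1278 of 11593 genes, and with TMM at 841 and 718, of which 335 and 717 were called with both scalings. Gene lists fixed before the data were examined gave the groups described next. The count of lowered genes was 728 without control library 1, 1935 without control library 2 and 431 without NASH library 2, and that of raised genes 139 without NASH library 1 and 150 without NASH library 2.

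**Figure D1:**
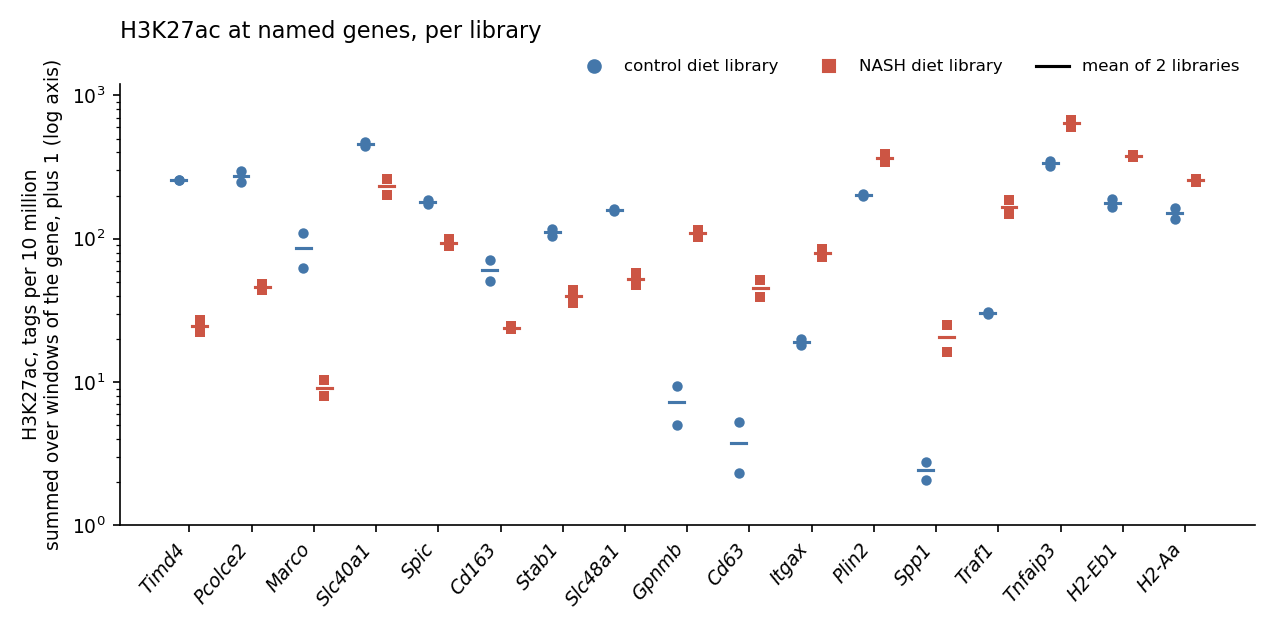
H3K27ac summed over the windows of 17 genes, in normalised tags plus 1 on a log axis, with 1 point per library and bars at the mean of the 2 libraries of each diet (blue, control; red, NASH). The NASH points of Timd4, Pcolce2 and Marco lie below and those of Gpnmb, Cd63 and Traf1 above both control points.

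Genes that define Kupffer cells lost H3K27ac under the NASH diet. The mark fell at 19 of 30 measured genes of the Kupffer cell identity list (20 adjusted over the list alone), and the other 11 did not pass. Timd4 fell from 256 ± 0.76 to 23.7 ± 3.32 normalised tags (log2 −3.10, SE 0.22, limma adjusted p = 6.72e-09). Pcolce2 fell from 274 ± 34.0 to 45.3 ± 2.91 (−2.28, SE 0.19, 3.55e-08) and Marco, a scavenger receptor for bacteria, from 85.1 ± 33.5 to 8.15 ± 1.72 (−2.91, SE 0.35, 4.76e-06). Slc40a1, which encodes the iron exporter ferroportin, fell by 0.71 on the log2 scale (8.80e-05), the lectin gene Clec4f by 0.58 (4.67e-04) and Adgre1, which encodes the other sort marker F4/80, by 0.63 (7.80e-04). Other members of the list did not pass the test, among them the complement genes C1qa (−0.00), C1qb (−0.05) and C1qc (0.01), the growth factor receptor gene Csf1r (0.23), Cd5l (0.20) and Nr1h3, which encodes LXRα (−0.16). The list moved down against all other genes (camera adjusted p = 8.24e-10, median log2 change −0.48), and adjusted p = 0.600 with an estimated correlation. With TMM 12 of the 30 fell, and the decreases of Id1, Id3 and Irf7 were no longer called. The markers of B cells, dendritic cells and endothelium measured in the same libraries lay lower too, at medians of −0.52, −0.41 and −0.54.

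The scavenger and phagocytosis list, which shares Timd4, Marco, Cd163, Axl and Vsig4 with the identity list, had 5 of 14 measured genes lower and 1 higher (7 and 2 adjusted over the list alone), with a median of −0.35 and a camera adjusted p of 0.0162, and adjusted p = 0.600 with an estimated correlation. Stab1, a scavenger receptor of liver macrophages and sinusoidal endothelium, fell by 1.20 on the log2 scale (SE 0.23, adjusted p = 2.27e-04) and the haemoglobin receptor gene Cd163 by 1.04 (SE 0.29, 0.00447). Cd36, a receptor for fatty acids and oxidised lipoprotein, rose by 0.89 (SE 0.19, 0.0434). The Cd36 call ended with any 1 of the 4 libraries left out (adjusted p between 0.0727 and 0.313). Of 13 iron and heme genes, 5 fell, of which Slc40a1, Spic and Cd163 are also on the identity list, and the others did not pass (7 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.149, and 0.00907 without control library 1 and 0.0313 without NASH library 1). Slc48a1, a transporter of heme, fell from 157 ± 3.65 to 51.7 ± 7.62 normalised tags (−1.31, SE 0.21, 3.25e-05), and Spic, a transcription factor of iron-recycling macrophages, from 180 ± 7.50 to 93.0 ± 7.99 (−0.66, SE 0.18, 0.00145). With TMM 4 fell and 2 rose on the scavenger list, and 4 fell and 1 rose on the iron list.

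Genes of lipid-associated and scar-associated macrophages gained H3K27ac. The mark rose at 11 of 26 measured genes of that list and fell at 1, Mitf (13 and 1 adjusted over the list alone), and with TMM it rose at 15. Gpnmb rose from 6.21 ± 3.16 to 108 ± 9.02 normalised tags (4.28, SE 0.35, limma adjusted p = 3.68e-07) and Cd63, a tetraspanin of late endosomes, from 2.77 ± 2.05 to 44.0 ± 8.61 (3.97, SE 0.47, 2.40e-05). Itgax, which encodes CD11c, rose from 18.1 ± 1.25 to 78.5 ± 6.62 (2.34, SE 0.28, 5.58e-05), and Plin2, a coat protein of lipid droplets, from 201 ± 6.07 to 365 ± 30.7 (1.14, SE 0.14, 3.51e-04). Spp1, which encodes osteopontin, went from 1.42 ± 0.50 to 19.5 ± 6.31 (3.36, SE 0.53, 5.17e-04), a call that ended without NASH library 1 (adjusted p = 0.0639). Mmp12, Cd9, Vim, Anxa2 and Fabp5 also rose. Trem2, the lipid receptor that marks such cells in other tissues, had a change of 1.02 that did not pass the test (adjusted p = 0.226), nor did that of Cx3cr1 (1.20, 0.169). The list moved up (camera adjusted p = 2.02e-12, median 0.82), and adjusted p = 0.600 with an estimated correlation. Mitf was called with the authors' scaling and not with TMM, and not without control library 1 or NASH library 2 (adjusted p = 0.135 at most). Spp1 is at once 1 of the 2 measured cholangiocyte markers, and the T cell gene Cd3d rose beside it.

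**Figure D2:**
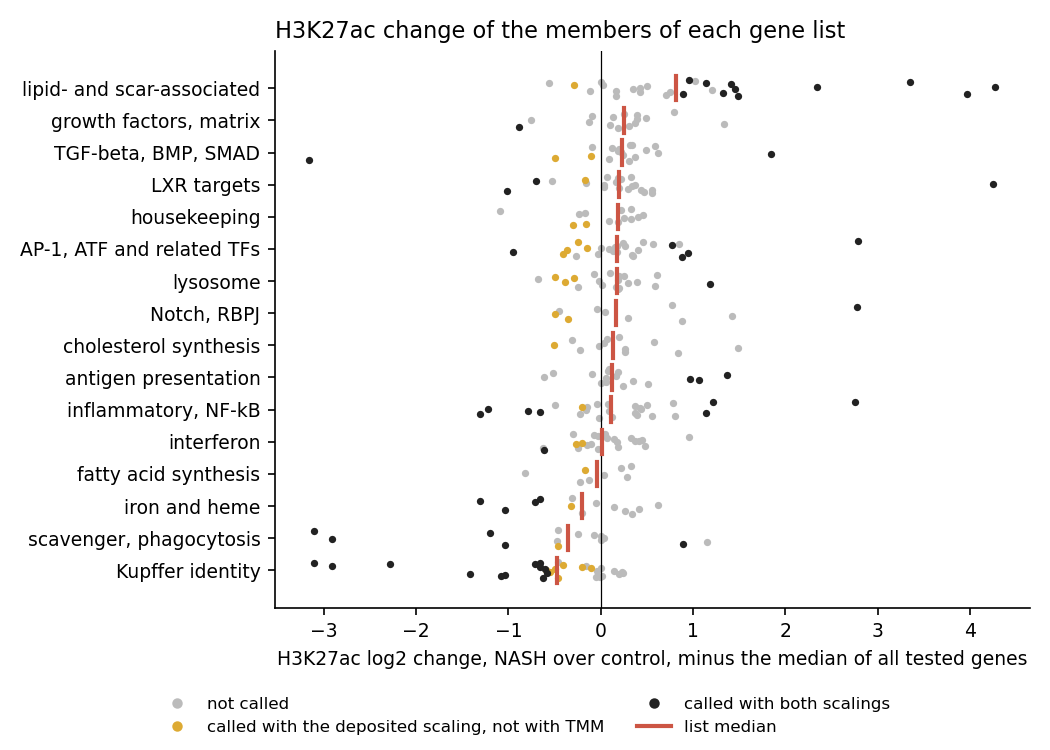
Log2 change of H3K27ac, NASH over control and relative to the median of all genes, for each measured member of 16 gene lists (points) with the list's median (red bar), where grey points were not called, yellow ones were called with the authors' scaling only and black ones with both scalings. Most called members of the Kupffer identity list lie below 0 and most called members of the lipid-associated list above it.

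Known target genes of LXR went in different directions. Of 21 measured, 1 rose and 3 fell (1 and 3 adjusted over the list alone), with a median of 0.20 and a camera adjusted p of 0.406, and with TMM 4 rose and 2 fell. Myo5a, an unconventional myosin, rose from 1.20 ± 0.19 to 33.2 ± 1.34 normalised tags (4.25, SE 0.48, adjusted p = 1.46e-05). The apolipoprotein gene Apoc1 fell by 1.02 on the log2 scale (SE 0.20, 1.84e-04) and Ptgs1, which encodes cyclooxygenase 1, by 0.70 (SE 0.17, 5.68e-04). The cholesterol exporters Abca1 (0.55, adjusted p = 0.0869) and Abcg1 (0.47, 0.300) did not pass, and did with TMM (0.0106 and 0.0311). Of 12 cholesterol synthesis genes 1 fell (1 adjusted over the list alone; camera adjusted p = 0.406), the feedback regulator Insig1, and of 8 fatty acid synthesis genes 1 fell, the desaturase gene Scd1 (2 adjusted over the list alone; camera adjusted p = 0.792). With TMM neither was called, while 1 cholesterol synthesis gene rose. The calls also ended without NASH library 1 or 2 for Insig1 (adjusted p = 0.122 at most) and without those or control library 1 for Scd1 (0.346 at most).

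Among inflammatory NF-κB genes, 3 of 26 rose and 5 fell (3 and 5 adjusted over the list alone; median 0.11, camera adjusted p = 0.387). Traf1 rose from 29.2 ± 0.59 to 167 ± 28.3 normalised tags (2.75, SE 0.23, limma adjusted p = 7.00e-07), Tnfaip3 from 334 ± 21.4 to 637 ± 54.2 (1.21, SE 0.12, 3.23e-05) and the chemokine gene Cxcl1 by 1.14. The cytokine genes Il6 (−1.22, SE 0.26, 4.67e-04) and Il10 (−0.79, SE 0.20, 0.00109) and the chemokine gene Ccl7 (−1.31) fell, as did Nfkbia, which encodes an inhibitor of NF-κB. With TMM 6 rose and 4 fell, and Nfkbia was not called. The calls ended without NASH library 2 at Ccl7 (adjusted p = 0.0865) and Nfkbia (0.124), and at Cxcl1 without either NASH library or control library 2 (0.182 at most). Of 22 interferon genes 3 fell, Cxcl10, Irf1 and Irf7 (3 adjusted over the list alone; camera adjusted p = 0.815), with a median of 0.01 and a mean of 0.05 against a test that pointed down. With TMM 1 rose and 1, Cxcl10, fell. The Cxcl10 call ended without NASH library 2 (0.0646), that of Irf1 without it or control library 1 (0.227 at most) and that of Irf7 without either NASH library or control library 2 (0.194 at most). In windows within 1 kb of the TSS Irf7 had a log2 change of 0.0027 before subtracting the median (0.996).

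On the antigen presentation list H3K27ac rose at H2-Eb1, from 177 ± 15.3 to 375 ± 7.83 normalised tags (1.37, SE 0.14, 3.66e-05), H2-Aa (1.06, SE 0.16, 0.00243) and H2-Ab1 (0.97, SE 0.20, 0.0271), which encode chains of the MHC class II molecules. They were the 3 called of 16 measured (3 rose and 1 fell adjusted over the list alone; 4 rose with TMM), and the list did not pass camera (adjusted p = 0.153, and 0.00971 without control library 2). Other class II genes did not pass, among them H2-DMa (−0.61), Ciita (0.35) and Cd74 (0.51), which was called with TMM. The H2-Ab1 call ended without control library 1 or either NASH library (adjusted p = 0.224 at most). Of 25 genes of AP-1, ATF and related transcription factors, 4 rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.336, and 0.840 with an estimated correlation). With TMM 7 rose and 1 fell (camera adjusted p = 0.0265 at the preset correlation, and an estimated one was not run with TMM). Atf3 itself rose from 362 ± 50.4 to 543 ± 12.7 (0.88, SE 0.13, 0.00330) and Runx2 from 5.42 ± 5.78 to 27.1 ± 3.09 (2.79, SE 0.55, 0.00431), while Cebpd fell by 0.95 (SE 0.23, 0.00103). Klf6 and Cebpb rose by 0.77 and 0.95, calls that ended without control library 1 at Klf6 (0.167) and without either NASH library or control library 2 at Cebpb (0.265 at most). The decreases of Batf3, Ets2 and Myc were not called with TMM, and that of Myc ended with any 1 library left out (0.183 at most).

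Notch4, a receptor of the Notch pathway, rose from 13 ± 4.01 to 76.3 ± 10.6 normalised tags (2.77, SE 0.32, limma adjusted p = 2.57e-05). It was the 1 gene that rose among 10 of the Notch list, where Hes1 and Maml2 fell (3 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.317), and with TMM 4 rose and 0 fell. In the TGF-β and BMP list, the receptor gene Bmpr1a went from 15.3 ± 6.69 to 0.54 ± 0.76 in its 1 window. Over that list 3 of 18 fell, the others being Id1 and Id3 (3 adjusted over the list alone). The median of the list was 0.23, however, and camera pointed up (adjusted p = 0.406). With TMM 1 fell, and Ski and Tgfbr1 were among the genes that rose (limma adjusted p = 0.0052 and 0.0183). Calls ended without control library 1 at Bmpr1a (adjusted p = 0.0996), without it or NASH library 2 at Hes1 (0.231 at most) and Id3 (0.146 at most), and without it or either NASH library at Maml2 (0.171 at most) and Id1 (0.0590 at most). Among 20 lysosomal genes Gla, which encodes α-galactosidase A, rose by 1.18 (SE 0.17, 0.00159), and Lamp1, Mitf and Neu1 fell with the authors' scaling and not with TMM (1 rose and 3 fell adjusted over the list alone; 3 rose with TMM; camera adjusted p = 0.785). The calls ended without NASH library 2 at Lamp1 (0.131) and without it or control library 2 at Neu1 (0.340 at most). Of 15 growth factor and matrix genes Hbegf fell by 0.88 (SE 0.30, 0.0113; 1 fell adjusted over the list alone; 1 rose and 1 fell with TMM; camera adjusted p = 0.387), until NASH library 2 was left out (0.292), and in its window with the highest mean the log2 change before subtracting the median was 0.036 (adjusted p = 0.973).

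Markers of other cells were measured in the same libraries. Among B cell markers Blk, a kinase of B cell receptor signalling, fell from 82.9 ± 9.71 to 14.2 ± 0.49 normalised tags (−2.17, SE 0.29, 1.24e-05) and Cr2 by 0.96 (SE 0.23, 9.49e-04), 2 of 4 measured. The dendritic cell gene Ccr7 fell by 1.20 (SE 0.29, 0.00160), 1 of 3 lowered among 5 with Batf3 and Zbtb46. Of 9 monocyte markers Nr4a1, a factor of patrolling monocytes, fell by 0.85 (SE 0.17, 1.48e-04) and Cd300e by 0.58 (SE 0.18, 0.00328), while Ly6c2 (0.63, 0.102) and Ccr2 (−0.24, 0.285) did not pass. Lbp fell by 1.70 (SE 0.25, 2.50e-05) and Fcna by 2.25 (SE 0.41, 2.63e-04) among 10 genes of peritoneal macrophages. In endothelium Stab2 and Dnase1l3 fell (2 of 5), in hepatocytes Cps1 (1 of 6), in stellate cells Ecm1 (1 of 4) and in neutrophils Csf3r (1 of 3). Cd3d rose among 4 markers of T and NK cells, from 3.35 ± 0.26 to 17.1 ± 6.77 in its 1 window, and Spp1 was the 1 of 2 in cholangiocytes. Adjusted over the list alone, 2 B cell, 3 dendritic, 3 monocyte, 5 peritoneal, 3 endothelial, 1 hepatocyte, 1 stellate and 1 neutrophil marker fell, and 1 gene each rose among monocyte, hepatocyte, T and NK cell and cholangiocyte markers. With TMM 2 B cell, 1 dendritic, 2 monocyte, 2 peritoneal, 1 endothelial, 1 hepatocyte and 1 stellate marker fell, and 2 monocyte markers and 1 each of hepatocytes, neutrophils, T and NK cells and cholangiocytes rose. None of the 5 lists with enough members passed camera, at adjusted p = 0.712 for monocytes, 0.406 for hepatocytes, 0.252 for endothelium, 0.315 for dendritic cells and 0.154 for peritoneal macrophages. The neutrophil median was −0.40 with a mean of 0.00 and the stellate median 0.02 with a mean of −0.17. Of 13 housekeeping genes Actb (−0.30) and Eef1a1 (−0.16) fell with the authors' scaling (2 adjusted over the list alone), and with TMM neither was called (camera adjusted p = 0.792, pointing down with a median of 0.19 and a mean of 0.03). In the window with the highest mean their log2 changes before subtracting the median were 0.15 and 0.31 (adjusted p = 0.792 and 0.507). Calls ended without NASH library 2 at Ecm1 (adjusted p = 0.0651), Cd3d (0.345) and Actb (0.265), without it or control library 1 at Cps1 (0.107 at most), without these or NASH library 1 at Stab2 (0.250 at most) and Zbtb46 (0.204 at most), without control library 2 or either NASH library at Eef1a1 (0.107 at most), and with any 1 library left out at Csf3r (0.250 at most) and Dnase1l3 (0.434 at most).

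The second comparison asked where LXR, ATF3 and P300 were bound in each diet. Within 20000 bp of Timd4 (gene at chromosome 11, 46810786 to 46844333), 13 LXR sites were listed for the control diet only, 3 in both diets and 0 for the NASH diet only. ATF3 had 6 control-only, 1 shared and 0 NASH-only sites there, and P300 10, 1 and 0. Around Marco (chromosome 1, 120474538 to 120505024) LXR had 6 control-only and 1 shared site, ATF3 4 and 0 and P300 4 and 0, with 0 NASH-only sites of each. The reverse held around Gpnmb (chromosome 6, 49036518 to 49058182), where LXR had 0 control-only, 1 shared and 6 NASH-only sites, ATF3 0, 0 and 7, and P300 0, 1 and 12. Spp1 (chromosome 5, 104435111 to 104441053) had 2 LXR and 4 ATF3 sites, all NASH-only, and 0 P300 sites. Around all 13617 protein-coding genes with a window, NASH-only sites outnumbered control-only ones. The counts were 28339 against 3567 for ATF3, 36165 against 3486 for P300 and 17124 against 9753 for LXR. An excess of NASH-only sites, of ATF3 and P300 above all, is thus not particular to the loci named here and below.

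The cholesterol exporter gene Abca1 is a direct LXR target (chromosome 4, 53030789 to 53159988). There 22 LXR sites were shared, 2 control-only and 6 NASH-only, beside 24 shared, 2 control-only and 54 NASH-only P300 sites. Abcg1 had 16 shared and 8 NASH-only LXR sites, with 4 shared and 32 NASH-only P300 sites. The strongest LXR site by the authors' enrichment score was shared at Timd4, Marco, Abca1, Abcg1, Mylip, Srebf1, Cd5l, Nr1h3, Clec4f, Id3, Trem2, Cd9, Atf3, Fosl2, Ets2 and Cx3cr1 in both diets. At Cd9 7 NASH-only sites of LXR, 7 of ATF3 and 12 of P300 were listed, and at Atf3 6, 5 and 8, against 1, 0 and 0 and 0, 0 and 1 control-only sites. Clec4f had 4 control-only, 11 shared and 5 NASH-only LXR sites, Cd5l 2, 13 and 1, Mylip 2, 3 and 3, Srebf1 0, 4 and 3, Nr1h3 1, 9 and 1, Id3 1, 8 and 1, Trem2 0, 3 and 2, Fosl2 1, 8 and 3, Ets2 2, 5 and 0, and Cx3cr1 1, 10 and 2. By score over the whole lists, the highest shared LXR and P300 sites scored 1094 and 1688 in an intergenic stretch of chromosome 2 at 98667034 to 98667241 and 98667049 to 98667252. It lies 1199530 bp from the TSS of Lrrc4c, the gene it was annotated to. These sites overlap the window that held 2.39% to 5.17% of the H3K27ac tags in windows. The highest control-only ones scored 524 and 443 near Esp38, on chromosome 17 beside the ribosomal RNA locus Rn45s. Among NASH-only sites the highest scores were 337 for LXR, near Rab20, and 347 for P300, at Rn45s. Control-only and shared P300 sites were also listed at Rn45s (scores 436 and 481). Whether the scores at Rn45s and at the chromosome 2 stretch reflect binding was not tested.

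**Figure D3:**
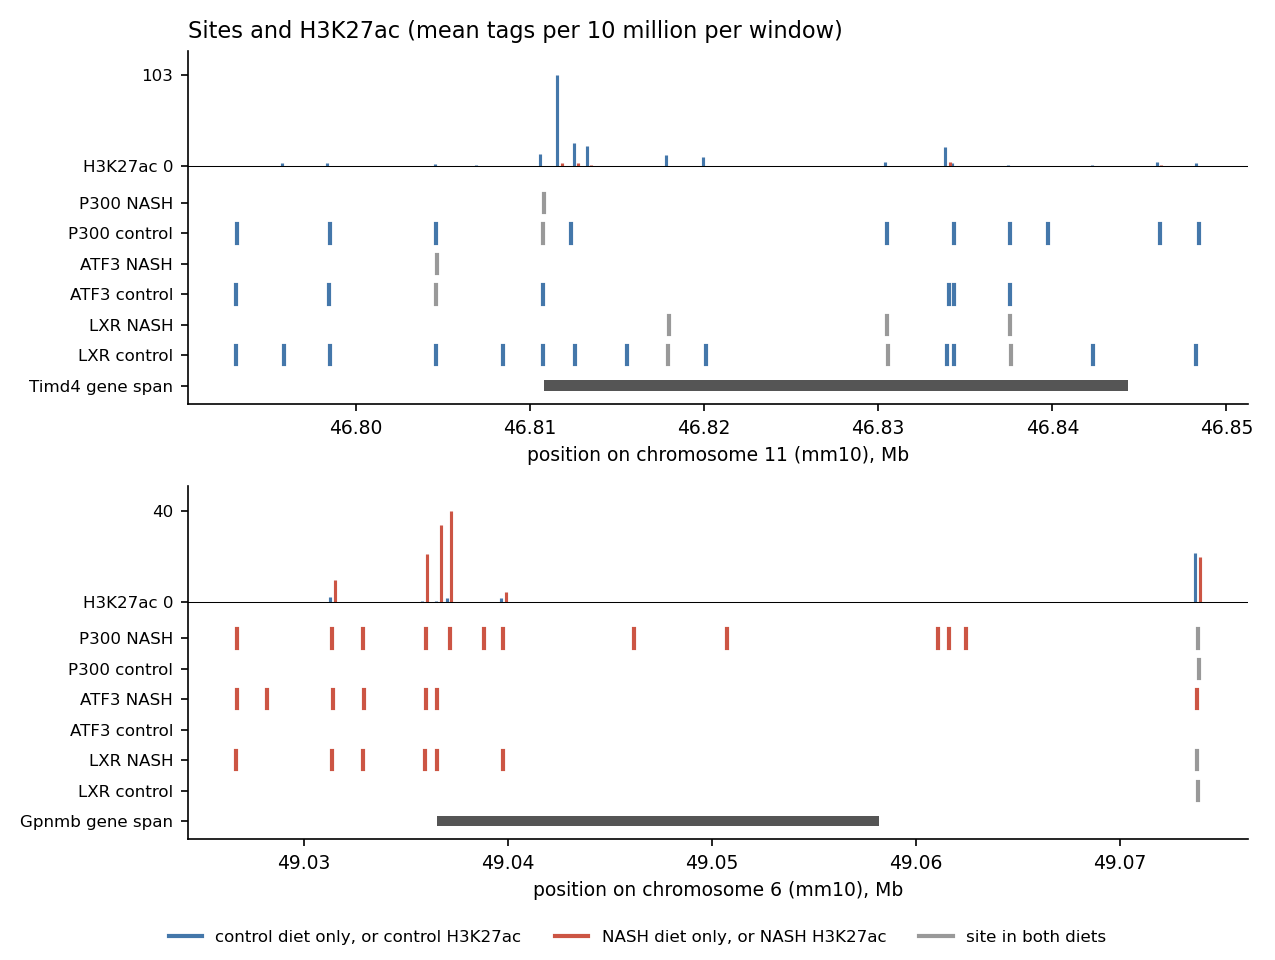
Maps of the Timd4 and Gpnmb loci on mm10 with 20000 bp on each side, by chromosome position in Mb, showing the gene span, the listed sites of LXR, ATF3 and P300 per diet and the mean H3K27ac of each window in normalised tags (blue, control; red, NASH). Of the listed LXR sites 13 at Timd4 are control-only and 6 at Gpnmb are NASH-only.

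Over the genome the lists were longer for the NASH diet, with 44463 and 51709 sites for LXR (1.16 times), 16109 and 38828 for ATF3 (2.41 times) and 25219 and 52628 for P300 (2.09 times). Of the control sites, 17.8% (exact 95% interval 17.4 to 18.1) of LXR, 17.4% (16.8 to 18.0) of ATF3 and 10.1% (9.73 to 10.5) of P300 overlapped no NASH site by at least 1 bp. Of the NASH sites, 29.3% (28.9 to 29.6), 65.7% (65.2 to 66.2) and 56.7% (56.3 to 57.1) overlapped no control site. With the longer list shortened to the other's length by rank, which makes the shares of both diets alike, they were 27.9% for P300 and 22.5% for LXR. The control share of P300 was 17.7% at a reciprocal overlap of 50%, 19.8% with centres within 100 bp and 6.54% on windows over 1 kb from a TSS. With 1 list per diet no replicate error is left, so the intervals cover counting error only and the difference between diets was not tested. The tag depth behind the lists is unknown here. Diet-only sites scored lower than shared ones of the same list. Median enrichment scores were 35 against 66 (control) and 30 against 53 (NASH) for LXR, and 24 against 31 and 35 against 72 for P300. For ATF3, 19.9% against 66.0% (control) and 56.1% against 85.1% (NASH) had the highest IDR score. A site below the threshold of the other list counts as diet-only, so a diet-only site need not be binding lost or gained.

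Of the LXR sites, 75.8% (75.4 to 76.2) overlapped a P300 site in the NASH lists against 47.5% (47.1 to 48.0) in the control lists, and ATF3 sites were overlapped by 54.9% (54.5 to 55.4) against 32.0% (31.6 to 32.4). P300 sites overlapped ATF3 at 54.5% against 43.8%, and LXR at 74.6% against 83.7%. ATF3 sites overlapped P300 at 73.8% against 68.5%, and LXR at 73.1% against 88.2%. NASH-only LXR sites held a NASH P300 site in 54.2% (53.4 to 55.0), and control-only LXR sites a control P300 site in 20.6% (19.7 to 21.5). For ATF3 these shares were 42.7% (41.9 to 43.5) and 9.68% (9.04 to 10.4). Such shares move with the length of the lists, which differed between diets.

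**Figure D4:**
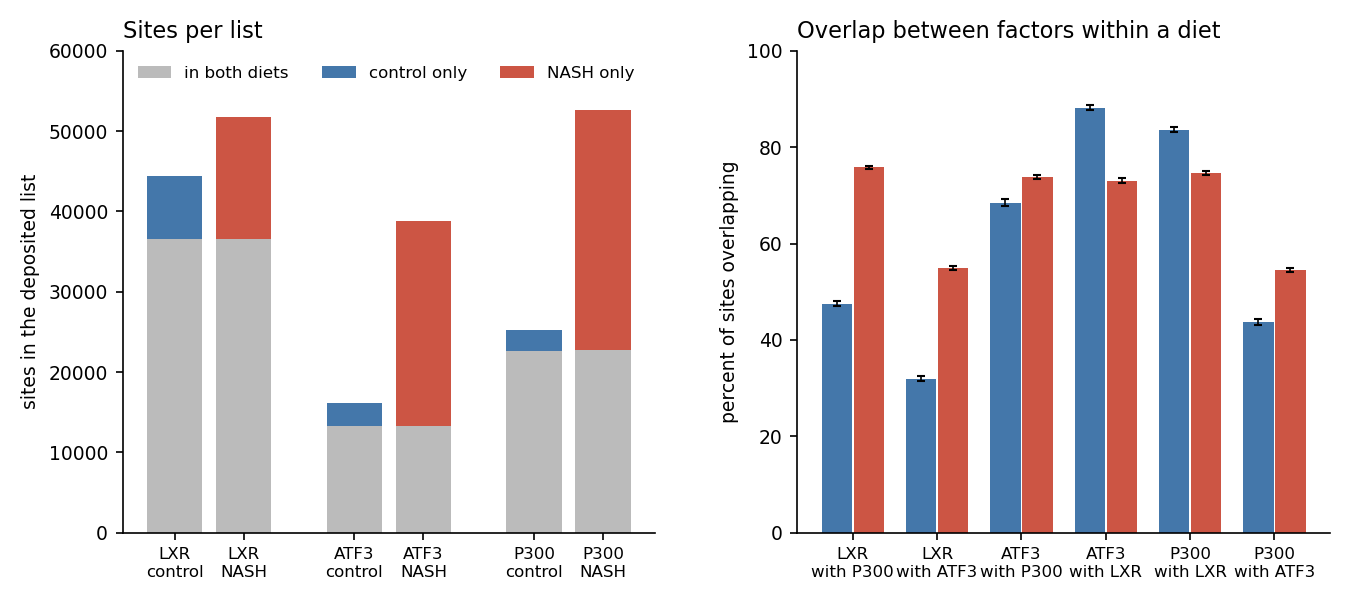
Sites per list of LXR, ATF3 and P300 in each diet, split into shared and diet-only sites (stacked counts), and the percentage of sites of each factor that overlap a site of another in the same diet with exact 95% intervals (blue, control; red, NASH). The NASH lists are longer for each factor, and the overlap of LXR with P300 is 75.8% against 47.5%.

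The last comparison set the sites against H3K27ac, which came from other libraries. Only sites on a window could enter. For LXR these were 62.5% of control-only, 86.6% of shared and 56.0% of NASH-only sites. In the same order they were 85.5%, 93.9% and 66.1% for ATF3, and 58.0%, 92.1% and 67.3% for P300. Whether sites, windows and H3K27ac were taken at the same time on the diet is not given in the sources used here. Windows with a NASH-only LXR site lay higher in the mark than other windows, at a median log2 change of 0.18 over 3627 windows, 262 raised and 92 lowered (camera adjusted p = 4.45e-04). Windows with a control-only LXR site lay lower, at −0.10 over 2465 windows, 17 raised and 239 lowered (0.0124), and the 20367 with a shared site lay at −0.01 (0.549). NASH-only ATF3 sites had a median of 0.12 over 8539 windows (0.00788) and control-only ones −0.14 over 1296 (0.0146), with 0.04 at shared sites (0.517). For P300 the medians were 0.07 over 9694 windows (0.0353), −0.08 over 810 (0.0232) and −0.01 at shared sites (0.549). The 6 calls at diet-only sites had adjusted p = 0.601 with an estimated correlation. The call at NASH-only P300 sites ended without control library 2 (adjusted p = 0.0587), without NASH library 2 (0.0883) and with TMM (0.0826), and that at control-only P300 sites without control library 2 (0.0587). With the strongest 50% of each list, for ATF3 the sites at its highest score, the calls at control-only ATF3 (0.121), control-only P300 (0.121) and NASH-only P300 sites (0.112) ended too.

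Of the 720 raised windows, 36.4% held a NASH-only LXR site, against 9.75% of the 33576 tested windows that were not called, an odds ratio of 5.30 (95% interval 4.51 to 6.20, two-sided Fisher's exact test, adjusted p = 4.80e-79). NASH-only sites were found in raised windows at 49.4% against 23.8% for ATF3 (odds ratio 3.13) and 54.0% against 26.7% for P300 (3.22). Of the 1651 lowered windows, 14.5% held a control-only LXR site against 6.58% (odds ratio 2.40, 2.07 to 2.78, adjusted p = 1.41e-27), 6.60% against 3.52% a control-only ATF3 site (1.94) and 4.91% against 2.17% a control-only P300 site (2.33). Shared sites were less frequent in raised windows (odds ratios 0.19, 0.29 and 0.13 for LXR, ATF3 and P300) and in lowered ones (0.55, 0.41 and 0.50) than in windows not called. The opposite pairs also lay below 1, at 0.34, 0.19 and 0.13 for control-only sites in raised windows and 0.55, 0.41 and 0.68 for NASH-only sites in lowered ones. All 18 tests of this family had an adjusted p of 3.91e-05 or less. With the strongest 50% of each list, control-only P300 sites in raised windows had an odds ratio of 0.43 (adjusted p = 0.0665). Neighbouring windows are not independent, which makes these p-values too small by an amount not estimated.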

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

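The tests on cell mixture were chosen only after the result was seen, while those on the ATAC-seq and factor lists were fixed before it.

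The windows themselves carry a signal outside the ChIP-seq measurements, since each names the ATAC-seq list it came from, and 19796 windows were on the control list only against 6836 on the 20-week diet list only. Deeper control ATAC-seq libraries alone would leave H3K27ac, from other libraries, changed alike at control-only windows and at windows of both lists with the same level. H3K27ac was lower by more than the bound of 0.1 at control-only windows in each of the 4 pairings of a NASH with a control library (difference of median log2 changes −0.18 to −0.25). This argues against depth as the only reason why windows were control-only. Diet-only windows lay higher by 0.29 to 0.37, so windows of both classes differed in the mark. The test therefore cannot say what made control-only windows the more numerous. Of 7972 tested control-only windows, 857 were lowered and 63 raised, and of 2074 diet-only windows 43 and 282. The ATAC-seq depth was not used here, so depth stays open as a cause of the larger number, beside a difference between the diets.

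The NASH lists of ATF3 and P300 were 2.41 and 2.09 times as long as the control lists, and libraries of higher depth or enrichment could lengthen a list without more binding. With that cause alone, H3K27ac at NASH-only sites would change as at shared sites of the same level. The smallest difference over the 4 library pairings was 0.042 for ATF3 and 0.0907 for P300, and the largest 0.103 and 0.121. Since these lie on both sides of the bound of 0.1, depth and diet cannot be told apart for either factor. For LXR, whose lists were 1.16 times apart, the difference was 0.20 to 0.23.

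H3K27ac was lower at Kupffer identity genes under the NASH diet, and cells of another type in the NASH sort could dilute their mark, although the gate on high F4/80 and Tim4 would remove most of them. Dilution by cells without the mark at any listed gene would lower these genes alike. Their changes were uneven (Cochran's Q per degree of freedom 14.8 over 30 genes, 8.03 without Timd4 and Marco, 2.40 over housekeeping genes), from Timd4 (256 to 23.7 normalised tags) to Cd5l (493 to 465). This argues against cells wholly without the mark as the whole cause. Cells with the mark at some listed genes would also lower the list unevenly, so the test cannot judge them. Added endothelial cells would raise their own markers, but the 5 measured had a median of −0.54 (SE 0.20; Dnase1l3 77.7 to 46.2). The highest of them, Pecam1, lay at 0.06 (SE 0.28). None of the 5 markers was called raised. Control cells carried the mark there too (median 51.3 normalised tags), so a loss in Kupffer cells could hide a rise from added cells. These values therefore cannot judge added endothelial cells. A share of dendritic cells or hepatocytes likewise stays open, with marker medians of −0.41 (SE 0.40) and 0.34 (SE 0.74). The dendritic marker Batf3, also on the AP-1 list, went from 540 to 337. Among hepatocyte markers Apoa1 (1.84), Ass1 (1.19), Apoa2 (0.38) and Ttr (0.31) lay above the median of all genes. Trf (−0.29) and Cps1 (−2.34) lay below it, and only Cps1 was called with the authors' scaling. Monocytes or cells newly derived from them, which may carry part of the mark, stay open too (median −0.0195, SE 0.28), since control cells already carried the mark at their markers (median 161 over 9, of which Cx3cr1 is also on the lipid-associated list), with Ly6c2 from 247 to 315, Cd44 from 372 to 337 and Ccr2 from 35.3 to 24.5. A change within the Kupffer cells themselves was not tested apart from these.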

How the results depend on the processing

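The count test with TMM, the TMM, RLE and upper-quartile scalings in limma, the fits without unplaced contigs and the 10 windows with most tags, and the identity list without Timd4 were chosen only after the results were seen, and the other alternatives were fixed before. The 20 named windows kept direction and call in every alternative, except Dnmbp without NASH library 1 or 2. Of the 68 named list genes, 40 kept the call with DESeq2, 49 with edgeR and TMM, 48 with limma and TMM, 52 without a filter, 30 of 67 with the window of the highest mean per gene, 21 of 53 with windows within 1 kb of the TSS, 38 to 58 with 1 library left out, and 35 with each library left out in turn. A library left alone in its group was assumed to vary like the other group. No paired reading was made, because same-numbered libraries hardly deviated together (correlation 0.040 over 2 pairs), and a replicate block gave 3890 changed windows (2837 lowered) and 2756 changed genes (2263 lowered), and let the iron and heme list pass (adjusted p = 0.0438). A window held a median of 6 to 11 tags, and the depth was not varied.

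Against 2371 changed windows (720 raised, 1651 lowered), DESeq2 gave 634 (428, 206), no filter 306 (136, 170), and a pseudocount of 0.1 1359 (426, 933). A test against a 1.5-fold change in edgeR gave 1286 with 554 lowered, and at least 20 tags in each of 2 libraries 1080 lowered, where fewer windows were tested. Raised windows numbered 1322 with RLE, 1326 with upper-quartile and 1357 with TMM factors in edgeR, and raised and lowered ones in limma 1191 and 902 with TMM, 1160 and 894 with RLE and 1187 and 997 with upper-quartile factors, each of which moves the median of all windows towards 0. With 1 library left out, changed windows ranged from 860 to 2996, raised from 176 to 841 and lowered from 684 to 2211. Against 1613 changed genes (335 raised, 1278 lowered), DESeq2 gave 705 (289 lowered), no filter 1030 (806 lowered), the window with the highest mean per gene 714 (217, 497), and windows within 1 kb of the TSS 375 (81, 294). Raised and lowered genes were 865 and 761 with RLE, 806 and 732 with upper-quartile and 857 and 764 with TMM factors in edgeR, 841 and 718 with TMM, 843 and 713 with RLE and 793 and 690 with upper-quartile factors in limma, and 613 were raised with totals over the windows in edgeR. With 1 library left out, changed genes ranged from 581 to 2229, raised from 139 to 385 and lowered from 431 to 1935. Of genes called lower, Hbegf (0.036), Actb (0.15) and Eef1a1 (0.31) turned to a log2 change above 0, before subtracting the median, in the window with the highest mean, and Irf7 (0.0027) in windows within 1 kb of the TSS. Except where fewer windows or libraries or another scaling entered, the cause was not tested.

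With an estimated correlation camera called 0 of 21 lists and 0 of 9 site sets, in place of 3 and 6 (1 and 0 at an unadjusted p under 0.05, smallest 0.0327 and 0.183), and fry, which tests a list against no change and not against other genes, called 2 lists (Kupffer identity and scavenger, both 0.0428, with the lipid-associated list at 0.0898). The lists called were 3 to 4 and the site sets 4 to 6 with 1 library left out. The peritoneal macrophage list passed with the window of the highest mean per gene (0.0416). The strongest 50% of each list, for ATF3 the sites at its highest score, left 3 site sets, with adjusted p = 0.121 at control-only ATF3 and P300 sites and 0.112 at NASH-only P300 sites, and 17 of the 18 Fisher tests (control-only P300 sites in raised windows 0.0665). Control sites absent from the NASH list and NASH sites absent from the control list came, for LXR, ATF3 and P300 in turn, to 21.1% and 32.2%, 19.9% and 66.8%, and 17.7% and 60.5% at a reciprocal overlap of 50%, to 22.2% and 33.1%, 21% and 67.2%, and 19.8% and 61.6% with centres within 100 bp, and to 12.7% and 23.3%, 14.2% and 57.3%, and 6.54% and 52.9% on windows over 1 kb from a TSS. In the strongest 50% of the lists they were 14.6% and 26.6% for LXR, 12% and 67.9% for ATF3, and 9.24% lost for P300, and in lists matched in length by rank 22.5% and 22.5% for LXR and 27.9% and 27.9% for P300. The shares of LXR sites with ATF3 and P300, of ATF3 sites with LXR and P300, and of P300 sites with LXR and ATF3 were, with centres within 100 bp, 29.6%, 40.6%, 81.7%, 60.5%, 71.5% and 38.7% in control and 50.5%, 69.1%, 67.3%, 67.9%, 67.9% and 50.1% in NASH lists, and in the strongest 50% 34.2%, 44.4%, 81.4%, 60.3%, 78.1% and 44.7% in control and 58.9%, 72.6%, 59.4%, 60.2%, 71.4% and 58.7% in NASH lists. Adding the peritoneal library, its comparison, the motif settings and ATF3 lists matched by rank were not run.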

Other observations

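Every test in this part was chosen only after the results were seen. The sites of the 3 factors were combined per window. NASH-only sites of none, 1, 2 or 3 of the factors LXR, ATF3 and P300 lay on 19706, 11459, 3945 and 837 tested windows, of which 1.05%, 1.55%, 4.46% and 19.0% were raised in H3K27ac, with median log2 changes relative to all windows of −0.04, 0.00, 0.16 and 0.68. Control-only sites of none, 1, 2 or 3 factors lay on 31611, 4111, 215 and 10 windows, of which 4.04%, 7.95%, 19.5% and 60% were lowered, with medians of 0.02, −0.10, −0.23 and −1.67. The last group holds 10 windows, and the trend over the numbers of factors was not tested.

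Around genes of the Kupffer cell identity list, control-only sites made up 57.4% of the diet-only LXR sites (81 control-only and 60 NASH-only), against a median of 34.4% (95% of lists between 25.0% and 44.4%) in 10000 random gene lists matched on site number, more than in 100% of them. The same share was 24.2% for ATF3, against 10.4%, and 33.3% for P300, against 10.2%, again above 100% of random lists. Around genes of lipid-associated and scar-associated macrophages the share was 13.7% for LXR, 4% for ATF3 and 5.17% for P300, at percentiles 0, 1.23 and 3.93. Scavenger and phagocytosis genes, which share 5 genes with the identity list, had percentiles of 95, 99.9 and 98.8, and iron and heme genes, which share 3 with it, 98.3, 79.4 and 99.4. Known LXR targets lay inside the range of 95% of random lists (percentiles 11.2, 30.6 and 58.1). The AP-1 and ATF factors (45.2, 40.3 and 84.2) and the antigen presentation genes (2.97, 50.0 and 15.4) did too. Inside that range as well were the lipid-associated list for P300, the scavenger list for LXR and the iron list for ATF3. These percentiles describe 1 pair of lists per factor and carry no replicate error.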
